A study of Mus musculus with 7 samples.

How the data were processed

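RNA was measured by mRNA sequencing of mouse cerebral cortex from C57BL/6 animals. There were 4 samples at embryonic day 17 and 3 samples from young adults. RNA was extracted with trizol and libraries were made with a standard Illumina mRNA kit, per the labels' protocols. CASAVA 1.7.1, TopHat 1.0.13, Bowtie 0.12.7.0, HTSeq 0.5.3p3 and SAMtools 0.1.7a are named, without role or order, in the submitters' processing notes, which also name the mm9 build of the mouse genome. Whether the counting used strand is not given in the sources used here, so reads of a gene and of an overlapping antisense partner cannot be told apart. Whether each sample came from 1 animal is not stated in the labels, so p-values measure the spread between these samples.

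A table of genes and a table of exons were used, each with 1 column per sample. The deposited gene values are variance-stabilized values on a log2-like scale, made by the authors from gene read counts. The tool that made them is not given in the sources used here. The scale follows log2 at high values and is compressed at low ones, with 1 shared value for genes without reads. A difference of 1 is close to 2-fold for well expressed genes and understates the fold of genes with few reads. All 14 columns of both tables were used.

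The deposited exon values are a score that the file headers describe as 1 over a ratio, also variance-stabilized by the authors. From the values, the score steps through whole numbers, and each whole number behaves as the gene's read count divided by the exon's read count. Over genes with at least 5 exons, 1 over the whole number summed to a median of 1.18 in embryonic replicate 1 and 1.21 in adult replicate 1. Among 47257 exon values whose whole number could reveal it, 96.1% were reached by some whole number of exon reads out of the recovered gene count, against 7.15% after the gene counts were moved by up to 200 reads. A higher exon value therefore stands for a smaller share of the gene's reads in that exon. The comparison had been planned for plain exon expression. It was run on the deposited exon values as planned and is reported as exon shares, computed as 100 divided by the whole number, with 0 taken as 1. Shares are coarse where the whole number is small. Reads that cross a junction can be counted in more than 1 exon, and a change in a large exon moves the shares of the others.

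Because each column is 1 smooth function of whole numbers with 1 scale per sample, the read counts behind the gene values were recovered. In every sample over 99.99% of gene values came out within 0.1 of a whole number. Values without reads and the lowest steps of each column were assigned their whole number, so they pass by construction. Later steps were fitted on steps already rounded, so this share alone does not check the counts. In simulated columns 99.98% of values were recovered exactly. The recovered counts summed to 18444270, 22575946, 21253466 and 21641240 reads in embryonic replicates 1 to 4 and to 22917238, 23606524 and 22734207 reads in adult replicates 1 to 3. Levels in the text are recovered counts per 1000000 reads in genes (CPM), given as mean ± SD. CPM and exon shares describe levels only, and the tests used the deposited values. Read duplicates could not be removed, so counts cover sequenced reads, not molecules.

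Replicates were compared before averaging. Pairs of samples of 1 group differed by a chi-square per degree of freedom of 4.83 to 17.7 over genes with at least 20 reads, which is more than counting alone gives. Whether samples share a library preparation or a run was not tested.

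Adult was compared with embryonic cortex in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with a mean-variance trend, all 7 samples and no covariate. Rows at the lowest value of their column in more than 3 of 7 samples were left out. Genes without reads in all 4 embryonic samples were thus left out, while genes without reads in only the 3 adult samples were kept. Without this filter 8508 genes were higher in adult and 7739 in embryonic cortex, against 8180 and 7736 with it. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Sets of genes were tested with camera at a preset correlation of 0.01 over 26 lists, 16 of pathways and cell classes of the cortex and 10 of markers of other cell types or tissues. Camera with an estimated correlation and fry were alternatives. Exon usage was tested with diffSplice, which sets each exon against the other exons of its gene, with the Simes test per gene for genes with at least 2 exons. Symbols of 26782 of the 36666 gene rows were found among GENCODE M21 names. Of the 508 fixed genes, 497 were found by symbol, 9 by an older symbol and 2, Rbfox3 and Ahsp, were not in the table.

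Genes to name were chosen by a rule fixed before the data were examined. It takes the 5 largest differences in each direction among called genes whose groups do not overlap. It takes from each list the 2 called members that differ most in the direction of most called members and 1 in the other direction. It adds Dcx, Mki67, Grin2a, Grin2b, Slc12a2, Slc12a5, Mbp, Gfap and Adarb1. For exon usage it takes the 10 genes with the smallest p and the 5 with the smallest p among 44 fixed genes, each with its most different exon. Some genes that the rule selects are not reported here, and counts over the named genes leave them out. Exon positions are those in the exon table's own names, on mm9. No coordinates were taken from the reference annotation, which is of another build and gave names and strand only.

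On simulated values for the 22828 tested genes, the gene test recovered 34% of genes shifted by 0.5 and 76% of those shifted by 1. It recovered 100% of those shifted by 2 but 88% of those shifted by -2, and called 10 unchanged genes. Just 50 genes were shifted by each amount, against 15916 called in the real data. The adjusted threshold was therefore stricter in the simulation, and these rates do not measure sensitivity or false calls in the real comparison. For 86407 simulated exons, 28% of exons shifted by 2 and 74% of those shifted by 4 were recovered, and 5 unchanged exons were called. Here too 50 exons were shifted by each amount, against 1711 called in the real data. The usage test recovered 64% of genes with an exon shifted by 2, but also called 267 unchanged genes of 7271. At shifts of 1, 2, 4 and -4 it recovered 4, 32, 47 and 50 of 50 genes. Most of its calls in the simulation were thus false, though the real data held more calls and their false share is not known. For that reason the exon p-values were also combined per gene with the Simes method, an alternative chosen after seeing the data, which called 8 unchanged genes in the simulation but recovered 28% of genes with an exon shifted by 2, against 64%, and 70% of those shifted by 4, against 94%.

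Alternatives fixed before the data were seen were no filter, a filter keeping the upper part of genes by mean, centring on the median, quantile normalization, moderation without a trend or with robust settings, leaving out each replicate, the replicate number as a block, treat with a null of 2-fold, an estimated correlation, fry and the F test of exon usage. Alternatives added after seeing the data were voom on the recovered counts, exons with at least 20 estimated reads, exons not equal in all samples, and the log2 of the recovered whole number. No sample was left out of the comparison. Python 3.11.15 was used for the recovery of counts.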

Results

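The transcriptome of the mouse cerebral cortex was compared between late embryonic development, embryonic day 17, and young adulthood, in 4 embryonic and 3 adult samples of the C57BL/6 strain. The samples held 18444270 to 23606524 reads in genes. Levels are given as counts per 1000000 reads in genes (CPM, mean ± SD, n = 4 embryonic and n = 3 adult samples), and differences as adult minus embryonic means on the log2-like scale of the deposited values, with limma's adjusted p.

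The first question was which genes change in the cortex between the embryo and the adult. The embryonic cortex was rich in mRNAs of dividing progenitors and of young neurons, and the adult cortex in mRNAs of synapses, ion channels, myelin and astrocytes. Of 22828 genes tested, 8180 were higher in adult cortex and 7736 were higher in embryonic cortex, and 8546 of these differed by at least 2-fold in their estimate. Tested against a null of 2-fold with limma's treat, 5136 genes passed. On the deposited scale, which compresses low counts, the largest increases among tested genes were in Mobp and Ttr. Genes without reads in all 4 embryonic samples were not tested. Mobp, a structural protein of myelin, rose from 0.0567 ± 0.0674 to 480.3 ± 84.7 CPM. Ttr, the thyroid hormone carrier transthyretin made by the choroid plexus, rose from 0.195 ± 0.152 to 604 ± 66.4 CPM. All 9 choroid plexus markers rose with it, so choroid plexus left on the adult cortex and a rise in cortical cells cannot be told apart. Scn4b, a sodium channel subunit, rose from 0.161 ± 0.134 to 255 ± 38.4 CPM, Gjb6, the astrocyte gap junction protein connexin-30, from 0.0502 ± 0.0583 to 69.1 ± 18.04 CPM, and Ptgds, prostaglandin D synthase, from 1.05 ± 0.274 to 511 ± 120.3 CPM. On the recovered counts in voom, Vip (9.88), Pvalb (9.63) and Cldn11 (9.37) rose by more than Ptgds (9.01). Mobp, Ttr and Gjb6 had no reads in at least 1 embryonic sample, where the counts were 0 to 3, 0 to 8 and 0 to 2 reads, and Scn4b had 1 to 8 reads there. The largest decreases on the deposited scale were in Igf2bp1, an RNA-binding protein of fetal tissues, from 39.3 ± 4.15 to 0.0997 ± 0.106 CPM (0 to 5 reads per adult sample), and Igfbpl1, from 403 ± 34.3 to 2.57 ± 0.794 CPM. The uncharacterized 2610109H07Rik fell from 209.7 ± 10.1 to 1.36 ± 0.161 CPM, the glypican Gpc2 from 396 ± 27.5 to 3.32 ± 0.478 CPM, and the surface glycoprotein Cd24a from 843 ± 82.5 to 8.87 ± 2.51 CPM. In all 10 genes the 3 adult values lay on one side of the 4 embryonic values, which the rule for naming them required. Their adjusted p ran from 1.22e-14 for 2610109H07Rik to 2.11e-09 for Igf2bp1 in limma.

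**Figure D1:**
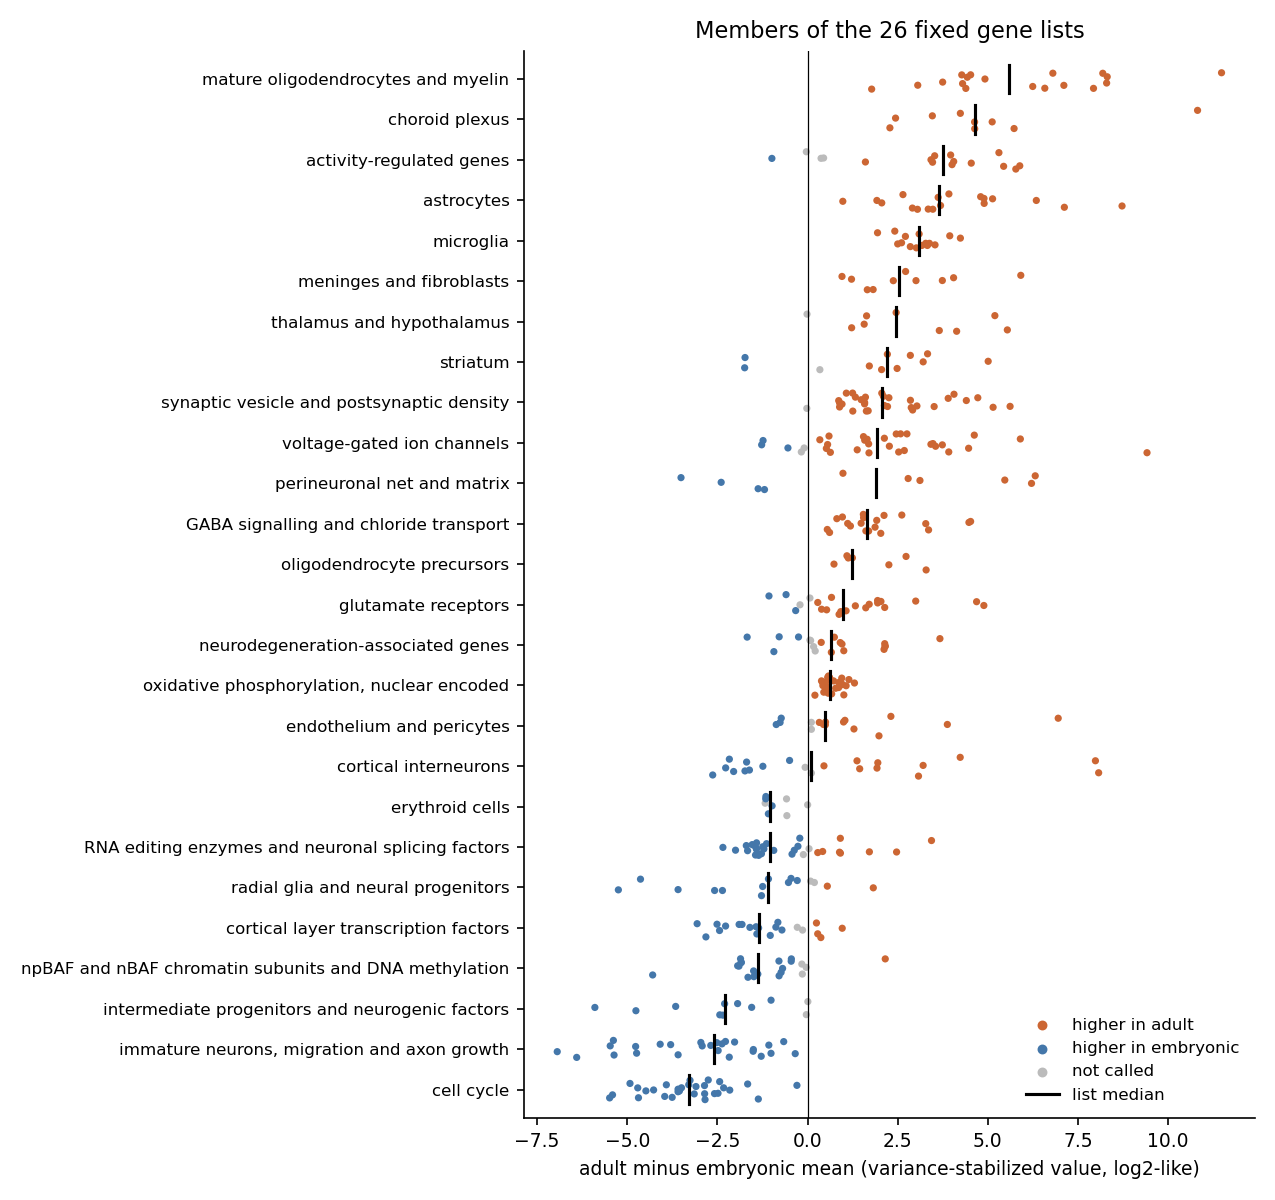
Adult minus embryonic mean of the variance-stabilized value (log2-like, horizontal axis) for each tested member of the 26 fixed gene lists (vertical axis, ordered by median). Each point is 1 gene, coloured by its limma call, and the black bar is the list median. All 30 cell cycle genes lie left of 0, and all 18 tested oligodendrocyte genes lie right of it.

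Genes of proliferation and neurogenesis fell. All 30 cell cycle genes were lower in adult cortex, among them Top2a, the DNA topoisomerase of dividing cells, from 144 ± 19.1 to 2.58 ± 1.19 CPM, and the proliferation marker Mki67, from 178 ± 35.4 to 3.34 ± 0.800 CPM (difference -5.41, SE 0.16, adjusted p = 2.77e-12). The cell cycle list had an adjusted p of 1.67e-12 in camera at the preset correlation and an adjusted p of 0.159 with an estimated correlation. Of 11 genes of intermediate progenitors and neurogenic factors, 9 fell and none rose. Eomes, the transcription factor of intermediate progenitors, went from 86.7 ± 10.6 to 0.924 ± 0.0352 CPM, and Neurog2, a proneural factor, from 49.7 ± 8.98 to 1.26 ± 0.196 CPM. The list's adjusted p was 0.000308, and its adjusted p was 0.21 with an estimated correlation. Of 15 genes of radial glia, the neural stem cells of the embryonic cortex, 11 fell and 2 rose (adjusted p = 0.0115, and adjusted p = 0.331 with an estimated correlation). The matrix protein Tnc fell from 337 ± 10.9 to 8.12 ± 3.76 CPM and the fatty acid binding protein Fabp7 from 435 ± 35.5 to 18.9 ± 14.8 CPM (10.4 CPM without adult replicate 2), whereas Hopx rose from 5.19 ± 0.726 to 18.9 ± 2.07 CPM.

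Genes of immature neurons fell as a group. All 26 genes of neuronal migration and axon growth were lower in adult cortex, with Igfbpl1 and Cd24a the most changed. Dcx, the microtubule protein of migrating neurons, fell from 1859 ± 204 to 38.6 ± 4.002 CPM (difference -5.47, SE 0.09, adjusted p = 4.68e-14). The list had an adjusted p of 5e-11 in camera and an adjusted p of 0.115 with an estimated correlation. Of 21 transcription factors of the cortical layers, 15 fell, 4 rose and 2 were not called (adjusted p = 0.000135, and adjusted p = 0.209 with an estimated correlation). Neurod6 fell from 487 ± 17.9 to 54.3 ± 5.52 CPM. Etv1, a layer 5 factor, rose from 31.4 ± 4.31 to 58.7 ± 11.4 CPM. When the samples were centred on their medians, 1 of the 21 rose and 17 fell.

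Regulators of chromatin and RNA were mostly higher in the embryo. Of 21 genes of chromatin remodelling and DNA methylation, 17 fell and 1 rose (adjusted p = 1.79e-05, and adjusted p = 0.153 with an estimated correlation). Ezh2, the histone methyltransferase of the polycomb complex, fell from 134 ± 7.93 to 5.78 ± 0.542 CPM and the methylcytosine dioxygenase Tet1 from 63.4 ± 11.6 to 14.9 ± 2.08 CPM, while the histone deacetylase Hdac11 rose from 47.7 ± 3.99 to 203 ± 7.83 CPM. Of 30 tested genes of RNA editing and splicing, 20 fell and 8 rose (adjusted p = 0.00811, and adjusted p = 0.285 with an estimated correlation). The splicing factors Hnrnpa1 and Srrm4 fell, from 464 ± 28.1 to 85.3 ± 5.20 CPM and from 208 ± 10.53 to 48.4 ± 2.93 CPM. Mbnl2, which regulates splicing in the adult brain, rose from 17.98 ± 2.597 to 191 ± 22.5 CPM, and Adarb1, an adenosine deaminase that edits glutamate receptor mRNA, rose from 61.4 ± 2.597 to 325 ± 11.8 CPM.

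**Figure D2:**
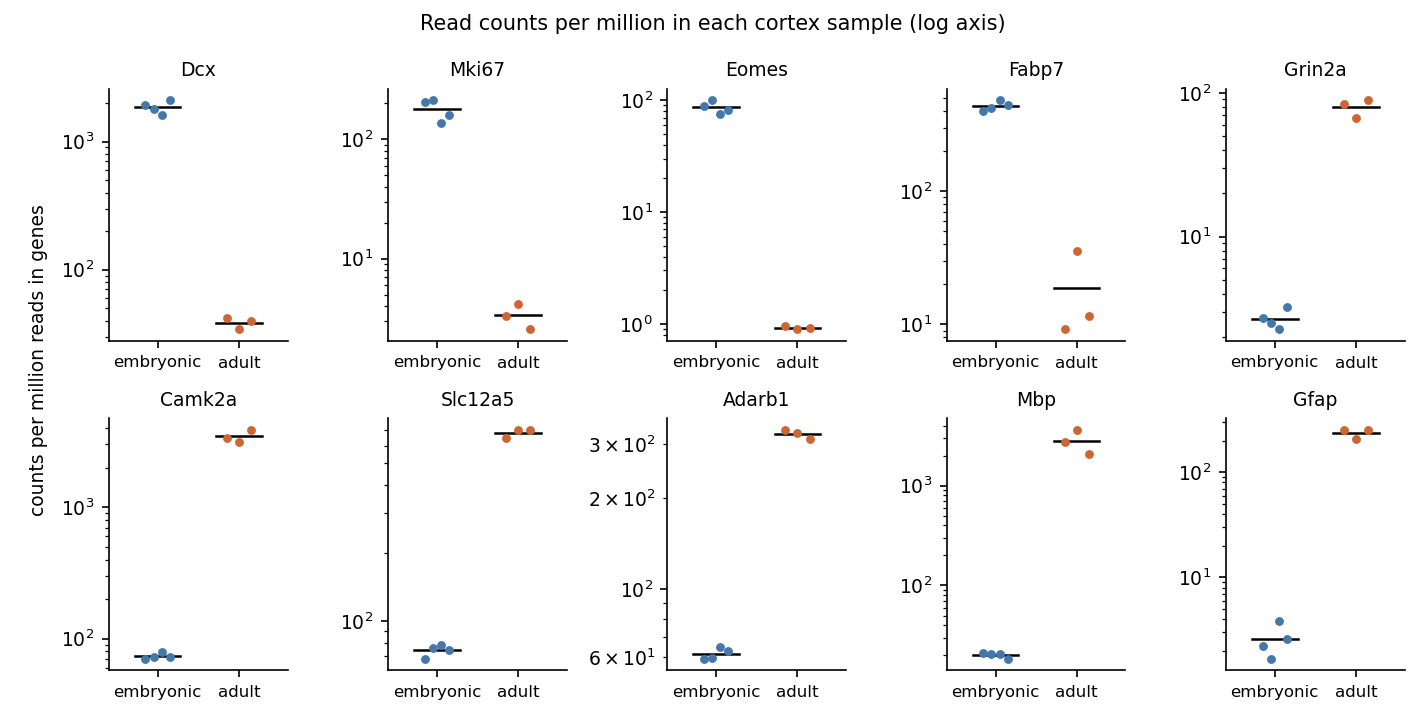
Counts per 1000000 reads in genes (vertical log axis, a separate scale in each panel) of 10 genes named by the fixed rule, in 4 embryonic and 3 adult cortex samples. Points are samples and bars are group means. Dcx, Mki67, Eomes and Fabp7 are higher in every embryonic sample, and the other 6 genes in every adult sample.

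Genes of synaptic transmission rose. Of 31 genes of synaptic vesicles and the postsynaptic density, 30 rose and none fell. Camk2a, the kinase subunit of excitatory synapses, went from 73.7 ± 4.20 to 3464 ± 385 CPM (difference 5.62, SE 0.08, adjusted p = 1.91e-14) and neurogranin (Nrgn) from 35.6 ± 8.60 to 1196 ± 74.3 CPM. The list's adjusted p was 1.1e-11, and its adjusted p was 0.115 with an estimated correlation. Of 22 glutamate receptor genes, 17 rose and 3 fell (adjusted p = 0.000763, and adjusted p = 0.159 with an estimated correlation). The NMDA receptor subunits Grin2c and Grin2a rose from 1.81 ± 0.133 to 65.9 ± 7.04 CPM and from 2.68 ± 0.412 to 79.7 ± 11.5 CPM. Grin2b differed far less, with 98.2 ± 11.9 against 121 ± 12.7 CPM (difference 0.39, SE 0.10, adjusted p = 0.0031), and its call was lost when the samples were centred on their medians. The kainate receptor subunit Grik3 fell from 295 ± 17.5 to 133 ± 14.5 CPM.

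All 20 genes of GABA signalling and chloride transport rose (adjusted p = 9.6e-08, and adjusted p = 0.115 with an estimated correlation). The receptor subunit Gabrd rose from 2.18 ± 0.586 to 56.4 ± 3.45 CPM. The neuronal chloride exporter Slc12a5 (KCC2) rose from 74.0 ± 4.34 to 685 ± 33.3 CPM (difference 3.28, SE 0.08). The chloride importer Slc12a2 (NKCC1) rose by less, from 71.0 ± 8.48 to 118 ± 5.89 CPM (difference 0.81, SE 0.09). Of 32 voltage-gated ion channel genes, 27 rose and 3 fell (adjusted p = 2.4e-07, and adjusted p = 0.115 with an estimated correlation). Scn4b was the most changed, and the T-type calcium channel Cacna1h fell from 209 ± 14.9 to 81.0 ± 6.79 CPM.

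The 21 genes of cortical interneurons went both ways, with 10 higher and 9 lower in adult cortex, and the list did not differ as a set (adjusted p = 0.823 in camera). The neuropeptide Vip and the calcium-binding protein Pvalb, markers of mature interneuron classes, rose from 0.0136 ± 0.0271 to 28.6 ± 7.24 CPM and from 0.0459 ± 0.0377 to 47.3 ± 6.34 CPM, with 0 to 1 and 0 to 2 reads per embryonic sample. Dlx2, a transcription factor of interneuron precursors, fell from 32.3 ± 6.84 to 4.32 ± 0.549 CPM. Of 10 genes of the perineuronal net and matrix, 6 rose and 4 fell (adjusted p = 0.253). The link proteins Hapln1 and Hapln4 rose from 0.162 ± 0.141 to 23.2 ± 3.26 CPM and from 0.822 ± 0.0379 to 88.5 ± 2.98 CPM, and the proteoglycan versican (Vcan) fell from 355 ± 52.5 to 28.4 ± 2.23 CPM.

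All 27 nuclear genes of oxidative phosphorylation rose by small amounts, with a median difference of 0.61 (adjusted p = 2.88e-06, and adjusted p = 0.219 with an estimated correlation). Sdha rose from 172 ± 7.23 to 402 ± 31.2 CPM and Ndufb9 from 67.1 ± 4.42 to 141 ± 0.763 CPM. Centred on the sample medians, 25 of the 27 were called. Of 19 genes associated with neurodegeneration, 11 rose and 4 fell (adjusted p = 0.0325, and adjusted p = 0.222 with an estimated correlation), and the call of this list was lost after centring on the medians (adjusted p = 0.0525). The kinase Lrrk2 rose from 4.54 ± 0.878 to 61.9 ± 9.29 CPM and the prion protein gene Prnp from 153 ± 9.60 to 645 ± 21.3 CPM, while Mapt, which encodes tau, fell from 1805 ± 159 to 531 ± 30.8 CPM.

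Markers of glia rose. All 18 tested genes of mature oligodendrocytes and myelin were higher in adult cortex (adjusted p = 1.5e-08, and adjusted p = 0.159 with an estimated correlation). Besides Mobp, the tight junction protein Cldn11 rose from 0.295 ± 0.173 to 180 ± 47.4 CPM and myelin basic protein (Mbp) from 20.2 ± 1.18 to 2816 ± 781 CPM (difference 7.11, SE 0.14). All 7 genes of oligodendrocyte precursors rose (adjusted p = 0.00139, and adjusted p = 0.153 with an estimated correlation), with Sox10 going from 4.72 ± 0.759 to 50.4 ± 16.5 CPM and Gpr17 from 11.6 ± 0.216 to 81.2 ± 34.8 CPM. All 18 astrocyte genes rose (adjusted p = 4.7e-10, and adjusted p = 0.0605 with an estimated correlation). Besides Gjb6, S100b rose from 0.517 ± 0.184 to 116 ± 3.61 CPM and Gfap from 2.59 ± 0.925 to 238 ± 25.3 CPM. All 15 microglial genes rose (adjusted p = 4.4e-08, and adjusted p = 0.115 with an estimated correlation), among them Tmem119, from 0.671 ± 0.0655 to 18.9 ± 2.98 CPM, and Ctss, from 3.13 ± 0.321 to 54.1 ± 6.56 CPM.

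Of 16 genes of endothelium and pericytes, 11 rose and 3 fell (adjusted p = 0.026, and adjusted p = 0.159 with an estimated correlation). The transporter Slco1a4 rose from 0.169 ± 0.119 to 47.2 ± 5.20 CPM and Ly6c1 from 1.05 ± 0.252 to 20.3 ± 3.34 CPM, and the pericyte channel subunit Abcc9 fell from 23.8 ± 2.599 to 11.9 ± 0.929 CPM. Of 8 tested erythroid genes, 4 fell and none rose, and the list did not differ as a set (adjusted p = 0.112). The alpha globin genes Hba-a1 and Hba-a2, near-identical copies whose reads cannot be assigned with certainty, went from 367 ± 67.0 to 161 ± 65.6 CPM and from 356 ± 65.3 to 157 ± 64.4 CPM.

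Several markers of tissue next to the cortex were higher in the adult samples. All 9 choroid plexus genes rose (adjusted p = 9.9e-05, and adjusted p = 0.115 with an estimated correlation), led by Ttr and by Kl, from 0.313 ± 0.155 to 30.1 ± 5.79 CPM. All 10 genes of meninges and fibroblasts rose (adjusted p = 0.000308, and adjusted p = 0.199 with an estimated correlation), with Slc6a13 going from 0.0660 ± 0.103 (0 to 4 reads per sample) to 9.22 ± 0.708 CPM and Dcn from 0.591 ± 0.134 to 15.1 ± 4.37 CPM. Of 11 striatal genes, 8 rose and 2 fell (adjusted p = 0.00454, and adjusted p = 0.159 with an estimated correlation). The opioid precursor Penk rose from 7.59 ± 1.202 to 251 ± 11.7 CPM, and Ebf1 fell from 20.9 ± 4.30 to 5.36 ± 0.617 CPM. Of 9 tested genes of thalamus and hypothalamus, 8 rose and none fell (adjusted p = 0.0148, and adjusted p = 0.321 with an estimated correlation). The hypothalamic peptides Avp and Oxt had 0 or 1 read in each embryonic sample, against 31 to 362 and 29 to 285 reads in the adult samples.

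Of 16 activity-regulated genes, which neurons induce after firing, 12 rose and 1 fell (adjusted p = 0.000819, and adjusted p = 0.345 with an estimated correlation). Arc rose from 2.49 ± 0.449 to 219.8 ± 196 CPM and Egr4 from 0.170 ± 0.0857 to 25.3 ± 19.7 CPM, and Nr4a3 fell from 71.9 ± 10.49 to 35.9 ± 17.4 CPM. The spread between adult samples was wide, with 14 of the 16 genes highest in adult replicate 2. Without adult replicate 2, 12 genes rose and 2 fell, and the adult means of Arc and Egr4 were 107 and 14.1 CPM.

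**Figure D3:**
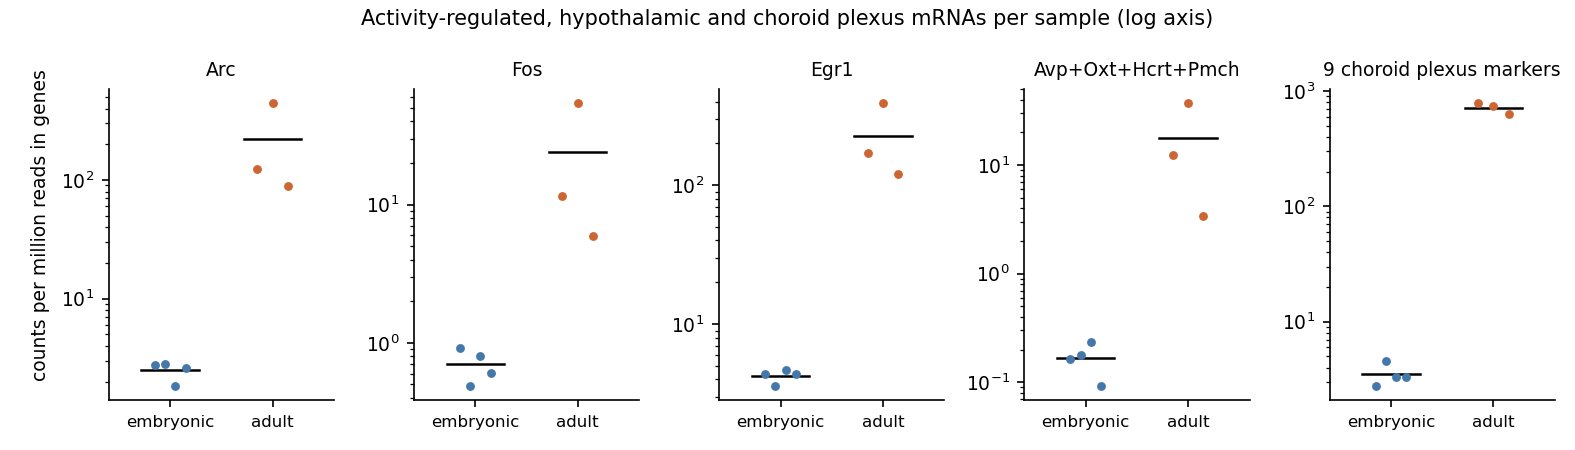
Counts per 1000000 reads in genes (vertical log axis, a separate scale in each panel) of Arc, Fos and Egr1, of 4 hypothalamic peptide mRNAs summed, and of 9 choroid plexus markers summed, in 4 embryonic and 3 adult samples. Points are samples and bars are group means. The peptide sum runs from 3.39 to 37.2 CPM between adult samples and the choroid plexus sum from 630 to 784 CPM.

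In all, 23 of the 26 lists differed as a set in camera at the preset correlation and 0 did with an estimated correlation, where 8 lists had an unadjusted p under 0.05. In fry, which tests a set's genes by themselves and not against the other genes, all 26 passed. The interneuron list passed too (adjusted p = 0.000339 in fry), with 10 genes higher and 9 lower. Passing fry therefore does not mean that the genes of a set move one way. Adjusted over the list alone, the counts of members called were the same except for neurodegeneration, with 12 higher, and striatum, with 9 higher. Centring on the sample medians moved the median difference of all genes by -0.18 and changed the share of calls that were higher in adult from 51.4% to 43.6%.

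The second question was which exons take a different share of their gene's reads in the 2 stages. Exons were named by the fixed rule. In Kalrn, which encodes a guanine nucleotide exchange factor of dendritic spines, the exon starting at 34152111 on chromosome 16 (mm9) held 1.02 ± 0.282% of the gene's reads in the embryo and 21.7 ± 2.89% in the adult. In Ncam1, the neural cell adhesion molecule, the exon at 49323244 on chromosome 9 went from 1.09 ± 0.123% to 14.5 ± 2.09%. The exon of Psd, an Arf exchange factor, at 46392144 on chromosome 19 went from 1.30 ± 0.179% to 9.76 ± 1.17%, and that of Macf1, a linker of actin and microtubules, at 123148250 on chromosome 4 went from 1.01 ± 0.125% to 3.86 ± 0.298%. Shares fell in the exon of Abr, a GTPase-activating protein, at 76281757 on chromosome 11, from 2.31 ± 0.215% to 0.0671 ± 0.0580% (0.0336% without adult replicate 2, with an estimated 9.67 reads per adult sample). They also fell in the exon of Ctnna2, the neuronal alpha catenin, at 76852281 on chromosome 6, from 4.88 ± 0.137% to 0.611 ± 0.241%. The exon of Ank3, the ankyrin of the axon initial segment, at 69456293 on chromosome 10 went from 3.62 ± 0.294% to 0.653 ± 0.0605%.

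Exons that were almost unused in the embryo were found in Arhgef2 at 88433419 on chromosome 3 (0.0412 ± 0.0239% against 2.54 ± 0.230%), in Arhgap32 at 32031834 on chromosome 9 (0.0559 ± 0.0208% against 1.48 ± 0.333%) and in Ank2 at 126864597 on chromosome 3 (0.0283 ± 0.0124% against 0.835 ± 0.0879%). The exon of the kinesin gene Kif1b at 148635269 on chromosome 4 rose from 0.0609 ± 0.0233% to 0.650 ± 0.0964%. The embryonic shares of Arhgef2 and Ank2 rest on an estimated 1.75 and 4.50 reads per sample, with that of Arhgap32 between them. All 11 exons were called in limma's exon test, with adjusted p from 1.01e-05 for Ncam1 to 0.0036 for Kif1b. The 3 adult shares lay on one side of the 4 embryonic shares for each. These exons were chosen by the usage test on the same values, so their calls and separation are no separate evidence.

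**Figure D4:**
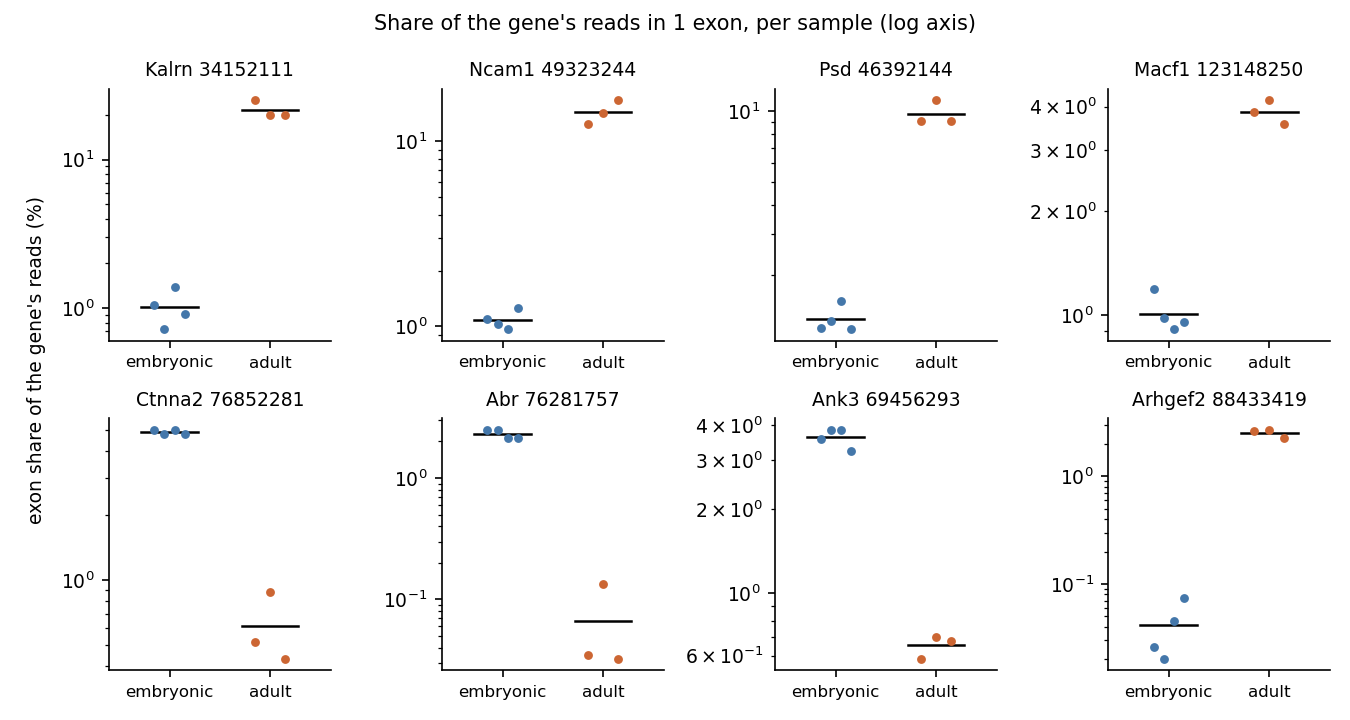
Share of the gene's reads in the most different exon (percent, vertical log axis, a separate scale in each panel) for 8 of the named genes, in 4 embryonic and 3 adult samples. Panel titles give the gene and the start of the exon on mm9, points are samples and bars are group means. The upper 4 exons and that of Arhgef2 hold a larger share in every adult sample, and those of Ctnna2, Abr and Ank3 a smaller one.

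Of 86407 exons tested, 889 held a larger share in adult cortex and 822 a smaller one, in 987 genes. Smaller shares numbered 493, 532 and 529 without embryonic replicate 2, embryonic replicate 4 or adult replicate 2. Larger shares numbered 581 and 548 without adult replicate 1 or 2. With the replicate number as a block, 194 exons held a larger and 122 a smaller share, though the labels do not pair the samples by number. Of 7271 genes, 2047 had an exon usage call, 36 of them among the 44 genes fixed in advance, and the same number of those 44 adjusted over the list alone. In simulated data most calls of the usage test were unchanged genes, so 2047 can be too high. With the exon p-values combined per gene, an alternative chosen after seeing the data, 817 genes were called, 28 of them among the 44. That combination also recovered fewer changed genes in the simulated data. Of the 1711 called exons, 94 had whole numbers that stayed at 3 or below, where a share moves only in coarse steps.

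Mapt was among the 44 genes and is described outside the rule, chosen after its values were seen. Its total fell in the adult, while 3 of its exons on chromosome 11 took a larger share. The exon at 104179471 went from 0.178 ± 0.0234% to 2.02 ± 0.0830% (adjusted p = 8.7e-05 in limma). The exons at 104148437 and 104151222 went from 0.00712 ± 0.00510% to 0.424 ± 0.116% and from 0.00680 ± 0.00283% to 0.302 ± 0.0926%, with an estimated 2.56 and 2.53 reads per embryonic sample.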

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

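All tests of explanations below were chosen after the results were seen, except that of exon position, whose bounds were set first. In 83 sets of 4 embryonic values, 4 held a sample far from the others, where chance gives about 1 in 20. Cd24a reached 967 CPM in embryonic replicate 4, against 799 to 806 in the others. Vip and Avp were at 0.0542 CPM in embryonic replicate 1 and Oxt at 0.0443 CPM in embryonic replicate 2, each a single read against 0 in the other embryonic samples.

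The first pattern is the higher level of mRNAs that mark neighbouring tissue in the adult samples. The summed mRNAs of the hypothalamic peptides Avp, Oxt, Hcrt and Pmch were at 12.3, 37.2 and 3.39 CPM in adult replicates 1, 2 and 3, and differed 10.98-fold between highest and lowest. Hcrt and Pmch had 1 read each in adult replicate 3, against 75 to 117 in adult replicates 1 and 2, so Hcrt and Pmch were not higher in every adult sample. The sum was higher in every adult sample, as it reached at most 0.235 CPM in an embryonic sample. Hypothalamic tissue carried into some adult dissections and a rise in cortical cells that differs between animals cannot be told apart, because how far such genes vary between animals is not known. For the choroid plexus, all 9 markers rose, as tissue left on the adult cortex would give, and their sum differed 1.25-fold between adult samples, so such tissue and a rise of the same genes in cortical cells with age cannot be told apart.

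The second pattern is the set of exons with another share in the adult. Rounding at whole numbers of 3 or below in every sample does not account for most of it. Such numbers were found in 5.49% of the called exons, and in 5269 of the 86407 exons tested. Exons at 3 or below in only some samples were not counted, so coarser steps there are not covered. For part of the set, too few reads cannot be told apart from a change in share. Of the called exons, 63.4% had at least 20 estimated reads in both groups. Exons under 20 reads on average made up 18.2% of the calls against 9.49% of the exons tested. Exons with a larger share in adult cortex lay nearer the 5′ end than those with a smaller share. The median relative position differed by -0.14 (95% bootstrap interval -0.21 to -0.06), over 757 and 681 exons. These lie in genes with at least 5 exons and a known strand. The interval treats exons as independent, although many share a gene, and does not measure the spread between samples. The difference lay between the bounds of 0.1 and 0.25 set in advance, though after a related measure of coverage per sample had been seen. That measure differed by 0.00575 between the group means (exact permutation p = 0.771, two-sided). First exons made up 17.7% of larger-share calls, 7.20% of smaller-share calls and 7.21% of all exons. Last exons were also more frequent among larger-share calls (13.9%) and smaller-share calls (11.3%) than among all exons (7.21%). A shift of read coverage towards one end and a change in exon use with age therefore cannot be told apart from the position alone.

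The third pattern is the higher level of activity-regulated mRNAs in the adult. It does not rest on 1 adult sample, because 12 of the 16 genes were still called higher without adult replicate 2. In that sample the median deviation of the 16 genes from the adult mean was 0.98, but the sample was picked for its high values and the genes vary together (estimated correlation 0.645), so chance spread and a cause in that sample cannot be told apart. It also had the highest sums of the hypothalamic peptides and of the myelin genes (8441 CPM, against 5906 and 4738.5 in adult replicates 1 and 3), and whether its tissue composition differed was not tested. The state or handling of the adult animals before tissue was taken and their age cannot be told apart, since both follow the same split of the samples, in which the lowest adult sum lay 3.50-fold above the embryonic mean.

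Other groupings of the 7 samples were tested for each count. Among the 35 splits into 4 and 3, only 1, the real one, gave as many genes higher in adult (8180, against 0 at most in another split), higher in embryonic (7736 against 0) or at least 2-fold different (8546 against 0). Another split reached at most 9854 genes at an unadjusted p under 0.05 in limma, and the real one 16418. Likewise only 1 split gave as many exons with a higher value in adult (822 against 62 at most), exons with a higher value in embryonic cortex (889 against 43) or genes with differential exon usage (2047 against 1120). The real split thus ranked first, at a share of 0.0286, the smallest that 35 splits can give. The comparison is lenient, because every other split mixes the stages and so puts the stage difference into the residual. The low counts of the other splits therefore do not show what spread between samples alone would give. For gene lists that differ as a set the real split gave 23 and another gave 22, so that, although only 1 split reached as many, the count says little about age.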

How the results depend on the processing

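The voom fit, the combined exon p-values and the further filters and scale of the exon values were chosen after the results were seen, and the other alternatives before. Of 1045 values of the 71 named genes under the alternatives, 1044 kept their direction and side of the threshold, and Grin2b lost its call after centring on the median. Most of these genes were picked as large called differences in the same data, so this stability was largely given by the choice. Among all 15916 called genes, 1179 lost their call after centring on the median and 1012 after quantile normalization. Leaving out 1 replicate lost 676 to 1088 of these calls. The 11 named exons, also chosen from the same data, kept their direction and side of the threshold in all 143 values. Of all 1711 called exons, 954 to 1321 were called again when 1 replicate was left out, and 263 with the replicate block. Of 101 counts of calls, 88 stayed within 1.5 times the main count. The stricter filter, which tests fewer genes, gave 4343 genes higher in adult, 3855 at least 2-fold different and 826 genes with differential exon usage. Treat with a null of 2-fold gave 5136 genes, as it asks for more. With an estimated correlation 0 lists differed. Leaving out 1 replicate gave 7691 to 8345 genes higher in adult, 7382 to 7579 higher in embryonic, 8272 to 8900 at least 2-fold different and 23 to 24 lists. It gave 493 to 1001 exons with a higher value, thus a smaller share, in adult, 548 to 1154 with a lower value and 1396 to 2985 genes with differential exon usage. The exon counts fell by over 1.5 times without embryonic replicate 2 (493), embryonic replicate 4 (532) or adult replicate 2 (529 and 548) and, for lower values, adult replicate 1 (581). They were highest without adult replicate 3, and the cause was not tested. Combining exon p-values per gene gave 817 genes.

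Nothing in the labels says that the replicate numbers pair the samples. Deviations of same-numbered samples correlated at 0.01, 0.06 and 0.04 in the gene table and at 0.05, 0.01 and 0.11 in the exon table, although each of the 3 embryonic samples came closest to the adult sample of its own number in the gene table, and 1 of the 3 in the exon table. With the replicate block, which uses 6 samples, 8344 genes were higher in adult. In that fit 122 exons had a higher and 194 a lower value in adult, against 822 and 889 in the main fit. Voom on the recovered counts gave 8326 and 7751 genes, and 15873 genes called in both fits had the same direction. Depth limits genes at a few reads, whose differences are compressed on the deposited scale.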

Other observations

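Families of genes that share a symbol stem were tested as sets with camera, a test chosen after the data were seen. Of 66 families with at least 20 tested members, 25 differed at the preset correlation and 0 with an estimated correlation. Genes of the ribosome were lower in adult cortex, with 43 of 46 Rpl genes and 35 of 43 Rps genes falling (adjusted p = 3.2e-08 and adjusted p = 5.4e-06, and adjusted p = 0.303 and adjusted p = 0.185 with an estimated correlation). Many ribosomal protein genes have processed copies, so their reads are uncertain. Of 21 Nup genes, nucleoporins of the nuclear pore, 20 fell, of 35 Rbm genes, RNA-binding proteins, 26 fell, and of 318 Zfp genes, zinc finger proteins, 212 fell and 35 rose. Of 81 Atp genes, ATPases and ATP synthase subunits, 56 rose and 9 fell. Of 86 Gpr genes, mostly G protein-coupled receptors, 50 rose and 16 fell, and of 22 Rgs genes, regulators of G protein signalling, 16 rose and 2 fell. These directions held in each family after centring on the medians and after quantile normalization, with 44 Rpl and 231 Zfp genes lower and 51 Atp genes higher after centring.

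The X-inactivation RNA Xist was abundant in all 7 samples, at 2241 ± 176 CPM in the embryo and 760 ± 76.2 CPM in the adult (difference -1.48, SE 0.09, limma). The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had at most 6 reads each in any sample. Genes named Gm and a number, many of them predicted genes or copies, took 10.3% to 11.02% of reads in embryonic and 6.89% to 7.18% in adult samples. Such loci can share reads with their parent genes, so these shares are uncertain. The measure of coverage along genes, the log2 of the whole number in the first minus the last part of the inner exons, had medians of 0.39, 0.39, 0.50 and 0.41 in embryonic and 0.39, 0.43 and 0.46 in adult samples over 3350 genes (exact permutation p = 0.771, two-sided). First exons made up 17.7% of the called exons with a larger share in adult cortex, 7.20% of those with a smaller share and 7.21% of all exons in genes with at least 5 exons. Last exons made up 13.9% and 11.3% of these calls, against 7.21% of all exons.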
